A study of Arabidopsis thaliana with 4 samples.

How the data were processed

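Chromatin was precipitated with an anti-GFP antibody from 2 g of whole seedlings of the 35S:ANAC060-GFP line in the anac060 mutant, per the labels' protocols. Seeds were stratified for 3 d and seedlings grown in constant light at 22 °C for 10 d on Murashige and Skoog medium with or without 6% glucose. The protocol also names 6% sorbitol, and which samples received it is not clear from the labels. Wild-type input DNA of each treatment served as the control. Groups were taken from the labels, with 1 library in each of 4 groups. No precipitate from untagged plants was used here.

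Reads were checked with FastQC and mapped to TAIR10 with BWA 0.7.15-r1140, per the submitters' processing notes. Peaks were called with MACS with the local background model turned off, per the file headers, which for the glucose list also give no shift model and a p threshold of 0.001. The MACS version is not given in the sources used here. Each list comes from 1 precipitate against 1 input, and no pooling is stated. The deposited score of each peak is the authors' own value. Its range fits the older MACS scale, -10 times log10 of the p-value, on which a p of 0.001 gives 30, with a ceiling of 3100. Glucose scores start at 30.02 with unbroken peak numbers. No-glucose scores start at 100.01, and the 4155 listed peaks carry numbers up to 7292 (57.0%). How the missing numbers were left out is not given in the sources used here. Scores were used to describe, rank and filter peaks within a list. Median ratios between the lists were taken only to describe their scales. With the local background model off, regions of uneven copy number or open chromatin can give peaks. Read counts were not used here, so depth is unknown.

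Peak positions were read as 1-based coordinates and restricted to the 5 nuclear chromosomes. Gene names and neighbourhoods came from the RefSeq gene table of TAIR10.1. That both share positions was checked by the drop of the gene-body share at peak centres against centres moved by 5 kb to either side, from 67.2% and 66.6% to 48.6% in the glucose list and from 66.5% each to 38.4% in the no-glucose list. The table used gives no strand, exons or transposable elements. The planned promoter upstream of a gene was therefore replaced by the 1 kb flank on either side of it. Classes of exon, intron and UTR, the exon and intron shares at ANAC060, and 12 planned motifs were not analysed here. All 206 genes of the 12 fixed lists matched by locus.

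Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks were shared if they overlapped by at least 1 bp, against 10000 random placements with widths and chromosomes kept. Score percentiles were compared by 100000 permutations. Peak centres were assigned to a gene body first, then a flank, another annotated gene or elsewhere, and the lists compared by Fisher's exact test. Gene lists were tested by one-sided Fisher's exact test against all other protein-coding genes with Benjamini-Hochberg adjustment over 24 tests, at a threshold of 0.05. Intervals are exact binomial at 95%, and intervals of differences use the normal approximation. The steps were tested on simulated data. Of 100 simulations with 2859 unrelated positions 7 had p under 0.05, and 857 planted shared peaks were recovered as 872.8. The unrelated positions were placed by the test's own rule, so this does not check whether random placement suits real peaks. Random gene lists passed in 1.1% of cases and lists with planted hits in 100%. The planted lists all held the same number of hits and so gave the same p, which makes the 100% a single result. Equal score groups passed in 2 of 100 simulations, and a planted shift of 0.2 was recovered as 0.199.

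Lists of genes, tests and the rule for named genes were fixed before the data were examined. The rule took, per list, the genes of the 10 highest peaks, of the 10 best-ranked shared peaks and of the 5 highest peaks of 1 list alone, up to 4 members per gene list, and ANAC060 and ABI5. Peaks that touched no gene and no 1 kb flank were passed over, also where their scores were higher. Where a peak had several genes, the one with the nearest end was named, since strand was not used. PYR1, OST1, ABI3, ABI4, HXK1, HAI2, HAI3 and UBQ13 and the peaks named outside the doubtful windows were added after their values were seen. Alternatives fixed beforehand were flanks of 500 bp and 2 kb, peak centres only, flank or gene body (for the gene lists), peaks above the median score, merging of peaks within 200 bp, 50% reciprocal overlap, centres within 250 bp, placement within 10 kb and exclusion of 1 Mb windows with under 100 protein-coding genes. A common minimum score of 100, equal numbers of peaks, exclusion of chromosome 2 from 3 to 4 Mb, peaks of 1 list alone, and flank or gene body for the counts of genes were added after seeing the data.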

Results

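Binding of ANAC060 to the Arabidopsis genome was mapped by chromatin immunoprecipitation and sequencing in 10-d-old seedlings grown with or without 6% glucose. ANAC060 is a NAC-domain transcription factor that has been linked to the sugar response through abscisic acid (ABA) signalling. A membrane-anchored form of the protein is known. The line carried ANAC060 fused to green fluorescent protein under the constitutive 35S promoter in an anac060 mutant, and the fusion was precipitated with an anti-GFP antibody. Wild-type Col-0 input DNA from seedlings of the same treatment, taken without antibody, was the control. The series held 4 libraries, 1 precipitate and 1 input per treatment, and the values were 2 peak lists, 1 per treatment. With 1 library per condition no difference between the lists has a replicate check. Every test below compares these lists, not the growth conditions, and intervals cover counting error alone. Read depth was unknown.

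The first question was how many sites each list held and which genes carried the strongest. The glucose list held 2859 peaks over 5.83 Mb, with a median width of 1673 bp, and the no-glucose list held 4155 peaks over 9.02 Mb, with a median width of 1784 bp. The highest-scoring peaks of both lists gathered on chromosome 2 between 3 and 4 Mb, around AT2G07565, AT2G07633 and AT2G07641, where a large insertion of mitochondrial DNA is known. This window took 7 of the 11 glucose peaks and 7 of the 14 no-glucose peaks at the highest score, 3100. Outside it, the no-glucose peaks at that score included AT3G20362, AT3G41762 and ANAC060 itself, all at 3100. The glucose peaks included AT3G20362 and a peak on chromosome 1 (24275673 to 24277139, TAIR10) beside AT1G65349 and the polyubiquitin gene UBQ13, both at 3100.

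Peaks outside the gene-poor windows and that part of chromosome 2 were ranked next, a choice made after the values were seen. Copy number was not examined, so regions of uneven copy number may remain among them. The AT2G01023 peak, for one, lay near the end of chromosome 2 (9555 to 10748 in the no-glucose list). Of those with a gene within 1 kb, the highest no-glucose peaks were at AT3G20362, ANAC060, LBD37, ARR4, NAC083, AT4G32020, AT2G01023, ERF4, RAP2.4 and ATPUP13. LBD37, a LOB-domain repressor of nitrogen-responsive genes, had a score of 2671, and ARR4, a response regulator of cytokinin signalling, had 2594. These peaks were 13014 and 13856 bp wide, with 4 and 5 genes near them. NAC083 had 2404, the ethylene response factor gene ERF4 had 2158 and the related RAP2.4 had 2056. The ARR4 and NAC083 centres lay 2513 and 2308 bp from the gene end, so a peak is named by its nearest gene and not by a known target. Among the glucose peaks that followed AT2G01023 (1853) were those of the purine permease gene ATPUP13 (1248) and the alternative oxidase gene AOX1A (845.0). MYB44 (776), a repressor of stress-responsive genes named MYBR1 in the annotation, was also among them. Others lay between, such as AT1G30780 (979) and AT1G77930 (950). The lists started at different scores, 30.02 with glucose and 100.01 without, so their lengths cannot be set against each other as deposited. At a score of 100 or more the glucose list had 674 peaks and the no-glucose list 4155, a ratio of 6.16 against 1.45 as deposited. The ratio was 8.28 at a minimum of 200, 9.54 at 300 and 9.32 at 500. Whether depth or the efficiency of precipitation differed between the libraries cannot be read from the lists.

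**Figure D1:**
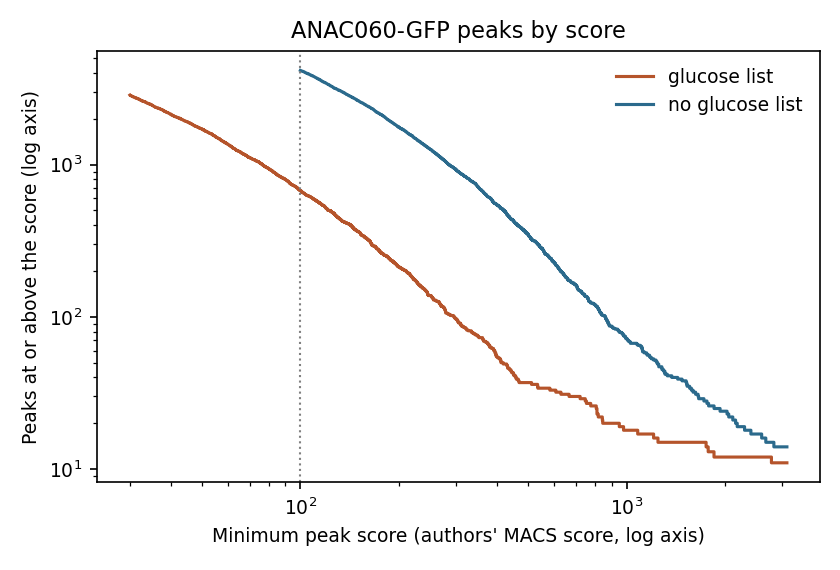
Number of peaks at or above each score (both axes logarithmic) in the glucose and no-glucose lists; the dotted line marks a score of 100. At that score 674 glucose peaks and 4155 no-glucose peaks were listed.

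ANAC060 was examined as the source of the transgene. A peak lay over the gene in both lists (chromosome 3, TAIR10), at 15972782 to 15975549 with a score of 171 in the glucose list and at 15972856 to 15975753 with the highest score, 3100, in the no-glucose list. Its rank was 283 of 2859 peaks with glucose, and it shared rank 1 of 4155 without. These peaks covered 95.8% and 92.9% of the annotated gene. Among genes of 2 to 3 kb touched by any peak, 5.13% in the glucose list and 4.06% in the no-glucose list were covered to 80% or more. ABI5, the basic leucine zipper factor of the ABA response, carried a lower-ranking peak at chromosome 2, 15206938 to 15208331, with a score of 32.27 (rank 2658) with glucose and at 15206686 to 15208375 with 147.81 (rank 2688) without. Both ABI5 peak centres fell in the annotated gene.

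The next question was whether the same places were bound in both treatments. Of the glucose peaks, 2117 of 2859 (74.0%, exact 95% interval 72.4 to 75.6) overlapped a no-glucose peak, and 2064 of 4155 no-glucose peaks (49.7%, 48.1 to 51.2) overlapped a glucose peak. Random placement of the glucose peaks on their chromosomes gave a mean of 395.9 shared peaks, so the observed number was 5.35 times larger (one-sided permutation p = 1e-04, the smallest that 10000 placements can give). Placement within 10 kb of each peak gave a mean of 958.9, and the observed number was 2.21 times larger. The 10 best-ranked shared peaks with a gene within 1 kb were 6 on the chromosome 2 window and those at AT3G20362, AT3G41762, AT2G01023 and ATPUP13. Outside the doubtful windows, again chosen after the values were seen, they included AT4G32020, AT5G61997 beside the auxin response factor gene ARF2, MYB44, AOX1A, the membrane-bound NAC factor gene NTL8 and the gibberellin receptor gene GID1B.

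Shared peaks ranked higher within each list. Their median score percentile was 58.3 against 30.1 for peaks found in the glucose list alone, and 67.5 against 35.2 in the no-glucose list (two-sided permutation p = 1e-05 each, the smallest that 100000 permutations can give). With shared peaks taken as those with centres within 250 bp, the gap between the medians fell from 28.2 to 12.9 points in the glucose list and from 32.3 to 16.1 in the no-glucose list, at the same p. From the lowest to the highest quintile of scores the shared fraction went from 53.8% to 93.0% in the glucose list and from 24.7% to 82.7% in the no-glucose list. Median peak width went up with it, from 1445.5 to 2526.5 bp and from 1449 to 3096 bp, and wider peaks overlap more easily.

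**Figure D2:**
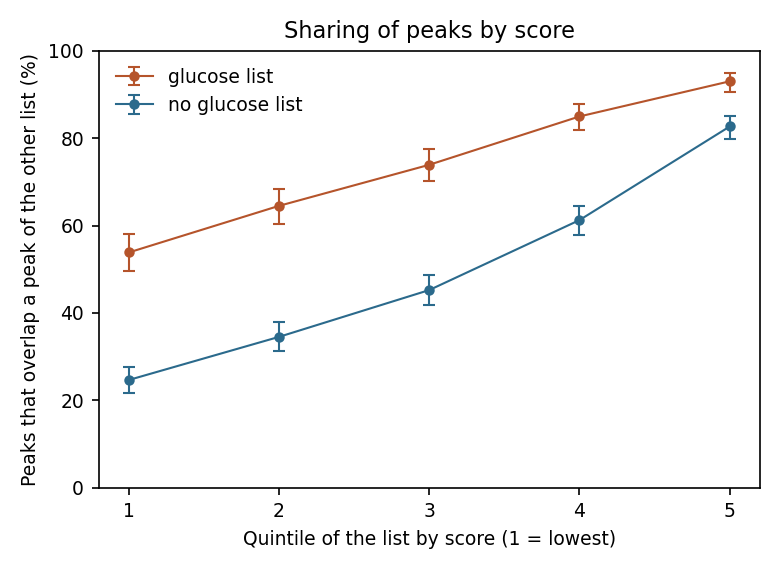
Share of peaks that overlap a peak of the other list (%), by quintile of each list's own scores, with exact 95% intervals. The share goes from 53.8% to 93.0% in the glucose list and from 24.7% to 82.7% in the no-glucose list.

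Peaks listed in 1 treatment alone numbered 742 with glucose (26.0%) and 2091 without (50.3%). This gap depends on the cut-offs. At equal numbers of peaks 62.0% of glucose and 59.7% of no-glucose peaks were shared, and at a score of 100 or more 91.8% and 15.3%. Of those with a gene within 1 kb, the highest of the no-glucose list lay by BT2 (score 942, chromosome 3, 17907726 to 17915306). BT2 is a BTB and TAZ domain gene of nutrient and sugar signalling. AT1G26920 (878), AT5G21940 (863), the galacturonosyltransferase-like gene GATL3 (826) and AT5G19875 (763) came next. The GATL3 peak was 8849 bp wide, with its centre 5404 bp from the gene end. In the glucose list they were AT5G40910 (534, chromosome 5, 16395529 to 16400501), ABCI4 in the chromosome 2 window (323), the exocyst subunit gene SEC10 (289), THH1 (223) and OBE1 (192). A peak missing from a list scored below that list's own minimum or was not called, so its absence is not absence of binding.

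The position of peak centres relative to genes was compared next. Centres were concentrated beside genes: 42.8% of glucose and 52.0% of no-glucose centres lay within 1 kb of a protein-coding gene and outside any gene body, where random placement gave 20.4% for both. In gene bodies lay 48.6% (46.8 to 50.5) of glucose centres and 38.4% (36.9 to 39.9) of no-glucose centres, both below the random means of 54.1% and 54.2% (two-sided permutation p = 2e-04, the smallest possible). The gene-body share of the glucose list was higher by 10.3 percentage points (95% interval 7.90 to 12.6; Fisher's exact test, adjusted exact p = 6.88e-17 over 4 classes), and its flank share differed by -9.18 points (adjusted exact p = 7.68e-14). The share elsewhere differed by -1.62 points (adjusted exact p = 0.0181). This last call did not hold: the difference was -0.66 points with 2 kb flanks (adjusted exact p = 0.0928) and 1.62 points the other way at a score of 100 or more in both lists (adjusted exact p = 0.165). Peaks found in the glucose list alone lay in gene bodies in 60.4% of 742 cases, against 44.5% of 2117 shared peaks (two-sided Fisher's exact test, p = 9.42e-14). In the no-glucose list the shares were 37.6% and 39.1% (exact p = 0.339). The tests and intervals between the lists take them as independent sets. Yet 2117 of 2859 glucose peaks overlapped a no-glucose peak, so these values are only approximate. Among shared peaks alone the gene-body share was 44.5% in the glucose list and 39.1% in the no-glucose list. Part of the gap therefore lay at sites found in both lists.

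**Figure D3:**
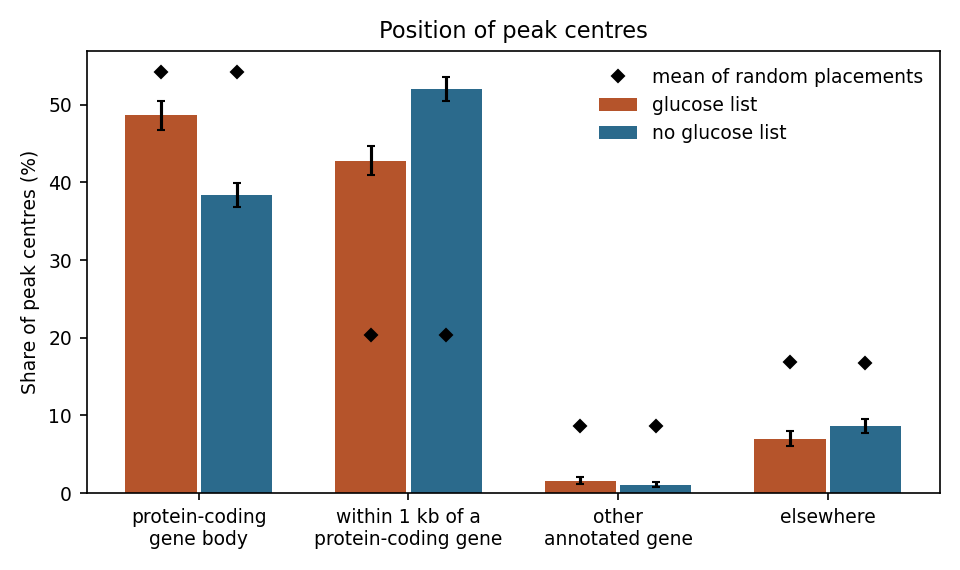
Share of peak centres (%) in protein-coding gene bodies, within 1 kb of such a gene, in other annotated genes and elsewhere. Bars are the lists with exact 95% intervals and diamonds the mean of random placements; the flank class holds 42.8% and 52.0% of centres against 20.4% at random.

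Genes with a peak that touched the 1 kb flank on either side were taken as the gene set of each list, and a peak inside the gene body alone did not count. Of 27444 nuclear protein-coding genes, 4880 (17.8%) had such a peak in the glucose list and 6940 (25.3%) in the no-glucose list. Both lists shared 3754 of these genes, where independent sets would share 1234 (odds ratio 20.3). A further 1126 genes were in the glucose set alone and 3186 in the no-glucose set alone. These counts depend on the cut-offs. At equal numbers of peaks they were 1699 and 1872, and at a score of 100 or more in both lists 108 and 5706.

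Rapid stress response genes had the highest odds ratio of 12 gene lists in both treatments. Of the 17 rapid stress response genes, 12 (70.6%, 44.0 to 89.7) had a peak in the glucose list and 16 (94.1%, 71.3 to 99.9) in the no-glucose list. Among them were MYB44 (scores 776 with and 1533 without glucose), ERF104 (154 and 1119), ERF5 (180 and 650) and ZAT12 (217 and 617), genes of ethylene response factors and of a zinc-finger protein. Over 2117 shared glucose peaks the median ratio of the no-glucose to the glucose score was 3.52. The no-glucose list held no score under 100.01, so for the 1498 shared glucose peaks under 100 a ratio above 1 was fixed in advance. Over the 619 shared peaks with a glucose score of 100 or more the median ratio was 2.26, so scores ran higher without glucose there too. Pairs of scores here and below therefore do not show a gain of binding at single genes. One-sided Fisher's exact tests gave adjusted exact p = 3.01e-05 with glucose (odds ratio 11.1) and 8.59e-08 without (odds ratio 47.4), over 24 tests. CBF2 and CBF3, neighbours on chromosome 4, were counted through the same peak. The highly expressed housekeeping genes, a control list, were also enriched, at 11 of 20 (55.0%, odds ratio 5.66, adjusted exact p = 0.000764) and 14 of 20 (70.0%, odds ratio 6.91, adjusted exact p = 0.000204), with ubiquitin UBQ3 (56.55 and 485), cyclophilin ROC1 (81.81 and 390), GAPC1 (105 and 388) and UBQ10 (85.97 and 302) among them. The photosynthesis genes, the other control list, were not, at 6 of 26 (23.1%, adjusted exact p = 0.554) and 5 of 26 (19.2%, adjusted exact p = 0.862), with LHCB4.1, CA1, RBCS2B and LHCA4 listed in both.

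ABA signalling genes were enriched in both lists, at 15 of 29 with glucose (51.7%, 32.5 to 70.6; odds ratio 4.97, adjusted exact p = 0.000204) and 17 of 29 without (58.6%, 38.9 to 76.5; odds ratio 4.19, adjusted exact p = 0.000675; one-sided Fisher's exact tests). These odds ratios were below those of the housekeeping control list as deposited and in the other alternatives. At equal numbers of peaks they were 4.97 against 5.66 with glucose and 4.76 against 6.66 without. Only among peaks above the median score were they higher, at 5.64 against 4.97 with glucose and 3.78 against 2.65 without. The members with the highest scores were the receptor genes PYL4 (46.67 with and 994 without glucose) and PYL5 (90.60 and 794) and the protein phosphatase 2C genes ABI1 (164 and 906), PP2CA (163 and 543), HAI3 (176 and 541) and HAI2 (170, in the glucose list alone). The receptor gene PYR1 and the kinase gene OST1 also had a peak in both, whereas ABI3 and ABI4 had none in either. Among glucose peaks above the median score the ABA signalling share was 37.9% against 9.77% of other genes (adjusted exact p = 0.000407). At 100 or more, with 674 peaks left, it was 13.8% against 4.88% (odds ratio 3.12, adjusted exact p = 0.239), and the housekeeping share was 15% against 4.88% (odds ratio 3.44, adjusted exact p = 0.244), so neither call was kept there.

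None of the other 8 lists passed the test. Sugar sensing and response genes had a peak in 5 of 23 cases with glucose and 7 of 23 without (adjusted exact p = 0.585 and 0.573), with cell-wall invertase CWINV1 (209 and 1175), HKL1 (88.70 and 546), DIN10 (36.67 and 542) and RGS1 (371, no glucose alone). Hexokinase HXK1 was listed in both, at 46.92 and 110. Membrane-tethered NAC genes had 6 and 7 of 15 (adjusted exact p = 0.126 and 0.179), ANAC060 and NTL8 (747 and 1310) with NTL6 and ANAC053. Ethylene signalling had 4 and 5 of 10 (adjusted exact p = 0.204 each), with the F-box genes EBF1 (534 and 560) and EBF2 (623, no glucose alone). Gibberellin and dormancy genes had 5 of 15 in each (adjusted exact p = 0.234 and 0.554), with GID1B (450 and 1311) and the DELLA gene RGA (48.60 and 341). ABA metabolism had 3 and 6 of 14 (adjusted exact p = 0.657 and 0.234), with CYP707A1 (46.45 and 449), ABA2 (332, no glucose alone) and NCED6 (209 and 245). ABA and osmotic stress responsive genes had 3 and 5 of 18 (adjusted exact p = 0.790 and 0.657), with ERD10 (49.98 and 373) and ERD1 (241, no glucose alone). R3 MYB trichome repressors had 1 of 6 in each, CPC (adjusted exact p = 0.790 and 0.862), and flavonoid genes 0 and 3 of 13, FLS1, MYB12 and MYB11 (adjusted exact p = 1 and 0.790). With peaks in the gene body counted as well, flavonoid genes had 1 and 4 of 13. Whether a list differed between the treatments could not be tested at this size. At most 6 members of a list were found in 1 treatment alone, for which the smallest two-sided exact p is 0.0312, or 0.375 adjusted over 12 lists.

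**Figure D4:**
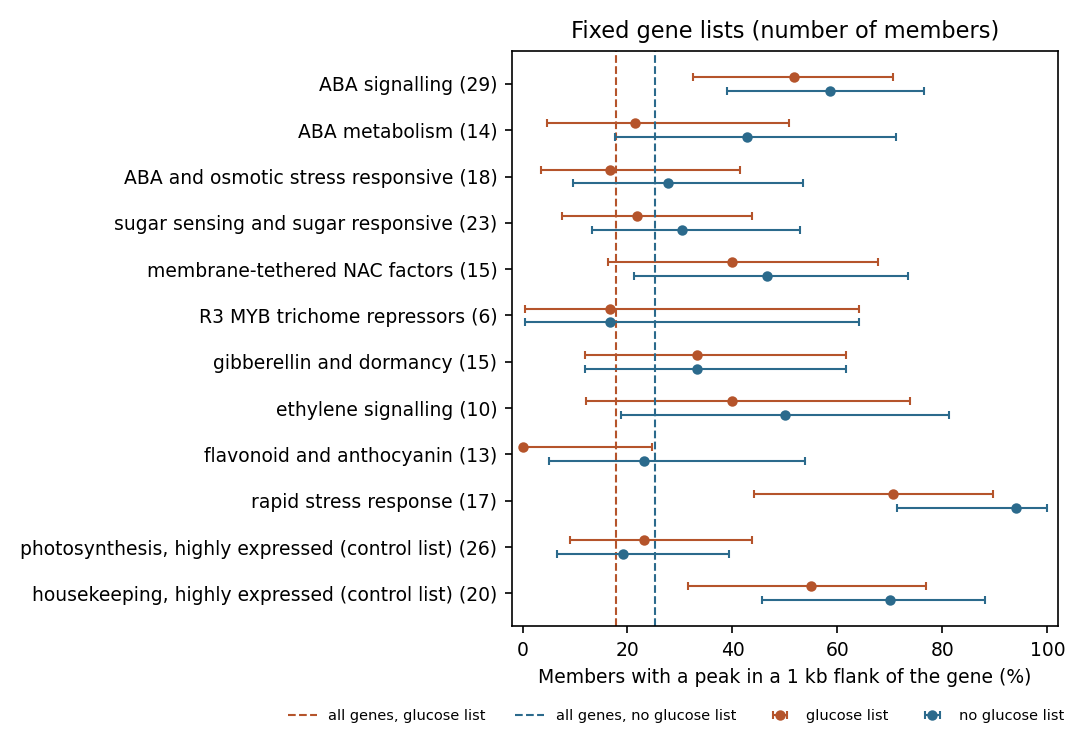
Share of the members of each fixed gene list with a peak in a 1 kb flank of the gene (%), peaks inside the gene body alone not counted, with exact 95% intervals; dashed lines are the shares over all protein-coding genes, 17.8% and 25.3%. Rapid stress response genes reach 70.6% and 94.1%, and the housekeeping control list 55.0% and 70.0%.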

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

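The position of peak centres differed between the lists in 3 classes by a test of the difference itself. That test takes the lists as independent sets, although most glucose peaks overlapped a no-glucose peak. Gene bodies held 10.255 percentage points more of the glucose centres, flanks differed by -9.184 points and the remaining space by -1.621 points, all glucose minus no glucose. The last of these turned to 1.621 points at a score of 100 or more in both lists (adjusted exact p = 0.165) and was -0.66 points with 2 kb flanks (adjusted exact p = 0.0928), so it did not hold. The tests weighed here were chosen after the result was seen, except that of glucose peaks at a score of 100 or more, which was set before its value was known.

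The gene-body share was highest among peaks found in the glucose list alone, at 60.4% against 44.5% of shared peaks. If a low score were the reason, the gap would close among higher scores. At 100 or more it was 1.392 points (95% interval -12.4 to 15.2), but only 55 peaks of the glucose list alone scored that high, so this test leaves the explanation open there. In the lowest quintile of scores, chosen after that value was known, the gap was 20.276 points (12.2 to 28.3, two-sided Fisher's exact test, p = 1.66e-06). Shared glucose peaks under 100 lay in gene bodies in 43.9% of cases, against 45.9% of those at 100 or more. Both argue against a low glucose score alone among those peaks. A shared peak had met a no-glucose peak of 100.01 or more, so shared peaks were also picked by their score in the other library. A weak signal in both libraries was thus not tested. Binding in gene bodies under glucose and weak false calls in transcribed genes both stay open, since each list comes from 1 precipitate.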

How the results depend on the processing

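No paired analysis was possible because each group held 1 library. Of the values that answer a comparison, 66 stayed the same, 12 counts moved, 1 lost its call, 4 gained one and 1 reversed. Tested values stayed the same if they kept their direction and their side of the threshold. Counts did so if they stayed within a fixed ratio of the main value. By this, 2859 against 4155 peaks was the same and 1429 against 2859 moved. The share of centres elsewhere, glucose minus no glucose, reversed to 1.621 points at a score of 100 or more and lost its call with 2 kb flanks (-0.66 points). That of other annotated genes (0.55 points, adjusted exact p = 0.0516) passed with flanks of 500 bp (0.742) and 2 kb (0.507), at a score of 100 or more (3.095) and in peaks of 1 list alone (0.987). It did not pass above the median score (0.843, adjusted exact p = 0.0661) or at equal numbers of peaks (0.350, 0.317). Without gene-poor windows and chromosome 2 from 3 to 4 Mb it fell to 0.328 points (adjusted exact p = 0.197). The cause of these changes was not tested. The share of peaks common to both lists stayed above random placement in every alternative run for it, which left out merging. It was 44.7% (centres within 250 bp) to 91.8% (score of 100 or more) of glucose peaks. The p was the smallest possible each time, so it cannot show how stable the excess was. The observed number was 2.21 (placement within 10 kb) to 25.6 times (centres within 250 bp) the random mean. The gene-body difference kept its direction in all alternatives, from 7.63 points (score of 100 or more) to 22.7 points (peaks of 1 list alone). Flanks of 500 bp and 2 kb could not change it, as gene bodies were assigned first. The counts that moved did so because the settings keep fewer peaks or a narrower target. Above the median score the lists held 1429 glucose and 2077 no-glucose peaks, with 2690 and 3823 genes and 1874 in both. With the peak centre inside the flank the genes numbered 2522, 3898 and 1602 in both. At a score of 100 or more, an alternative chosen after seeing the data, the glucose list held 674 peaks and 1342 genes, 1234 of them in both, and 1 of its 3 enriched gene lists, rapid stress response, passed. Of single gene lists, 165 values kept their call and 3 lost it: ABA signalling and housekeeping in the glucose list at that score, where fewer peaks were left, and housekeeping in no-glucose peaks above the median score (30%, adjusted exact p = 0.125). Some of the 165 had shares that could not change. A minimum of 100 leaves the no-glucose list as deposited, and equal numbers of peaks leave the glucose list as deposited. Motif tests, exon classes and the transposable-element part of the gene-poor exclusion were not run. Leaving out a library was not possible, and unknown depth limits every statement on a missing peak.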

Other observations

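Gene families defined by symbol were examined after the data had been seen, as 80 families with at least 20 genes and 160 tests. In the no-glucose list WRKY transcription factor genes had a peak in a 1 kb flank in 41 of 72 cases (56.9%, odds ratio 3.92, one-sided Fisher's exact test, adjusted exact p = 1.77e-06), MPK mitogen-activated protein kinase genes in 13 of 20 (65.0%, adjusted exact p = 0.0110) and ATG autophagy genes in 18 of 34 (52.9%, adjusted exact p = 0.0203). In the glucose list PUB genes, a symbol mostly of U-box proteins, passed with 13 of 23 (56.5%, adjusted exact p = 0.00268). In the other list of each, WRKY genes had 21 of 72 (29.2%), MPK genes 9 of 20 (45.0%, odds ratio 3.79), ATG genes 9 of 34 (26.5%) and PUB genes 10 of 23 (43.5%, odds ratio 2.27), none past the threshold, so the families are not shown to belong to 1 list. Between the lists, at equal numbers of peaks, 3 of the 80 families had enough members found in 1 list alone to pass if they stood out by themselves, so differences between the treatments were not testable for most. Those 3 did not pass.

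Of the tests below, those on the control lists and on coverage of ANAC060 were chosen after the result was seen. The enrichment of rapid stress response genes in both lists was set against high transcription. In the no-glucose list the upper bound of the photosynthesis share was 39.351%, under the lower bound of the stress share (71.3%). The upper bound of the housekeeping share there was 88.1%, above that bound. The control lists thus point different ways and expression was not measured here, so high transcription alone stays open. The housekeeping list, also highly expressed, reached 70%, so part of the peaks may come from open chromatin or antibody background common to any precipitation. This cannot be told apart from binding of ANAC060, because no precipitate from untagged plants was used here. It stays open for the ABA signalling genes too. Their odds ratios lay below those of the housekeeping list as deposited (4.97 against 5.66 with glucose, 4.19 against 6.91 without) and in the other alternatives. Only among peaks above the median score did they lie above (5.64 against 4.97, and 3.78 against 2.65). These differences were not tested.

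The ANAC060 peak of the no-glucose list, at the score ceiling, covered 92.901% of the gene, the lower of the 2 lists. Transgene DNA in the precipitated line and absent from the wild-type input would give a peak over most of the gene. Only 4.06% of touched genes of 2 to 3 kb were covered to 80% or more, so it is a candidate explanation for that coverage. Of the peak itself, 89.2% with glucose and 82.6% without lay in the gene, and the rest reached past it. Whether the transgene holds that flanking sequence was not examined. The same line gave both precipitates, and with glucose the peak had a score of 171 and rank 283 of 2859, so transgene DNA alone leaves the ceiling score in 1 list unexplained. It cannot be told apart from binding of ANAC060 to its own gene, since exons, introns and depths were not analysed here.

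A hypothesis from the highest peaks of the no-glucose list alone, such as BT2, was that genes induced by sugar starvation carry peaks more often without glucose. A list of 20 such genes was drawn up after those peaks had been seen, with BT2 and HSPRO2 left out. Its 3 genes shared with the fixed sugar list had been seen in that list's totals. Its prediction was set before the other members were looked up, and 1 such list was tried. In the no-glucose list 10 of 20 had a peak (odds ratio 2.96, one-sided Fisher's exact test, p = 0.0150) and in the glucose list 4 of 20 (p = 0.487). Of the members, 6 had a flank peak without glucose alone (TPS8, TPS11, GDH2, AKINBETA1, BAM9 and ProDH) and 0 with glucose alone, at equal numbers of peaks too (two-sided exact p = 0.0312). The TPS8 peak (977) scored above BT2 (942), the highest peak named from the no-glucose list alone. It therefore overlapped a glucose peak that did not touch the TPS8 flanks, and TPS8 counts here through the flank rule. A split of 5 to 0, as without TPS8, has a two-sided exact p of 0.0625, over the threshold. Whether the peaks of those 5 genes also overlapped a glucose peak outside the flanks was not examined. Among the 80 families, ATH genes, a symbol that mixes transporters and thioredoxins, split as 8 without glucose alone and 0 with (exact p = 0.00781), and PUB genes as 0 and 6 (exact p = 0.0312), neither past correction. Each treatment had 1 library, so the starvation result may be a chance split and stays a hypothesis. Open chromatin or antibody background cannot be told apart from binding here either, as no precipitate from untagged plants was used. The housekeeping control list had higher shares than the starvation list, at 14 of 20 without glucose (odds ratio 6.91) and 11 of 20 with (odds ratio 5.66).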
